A study of Homo sapiens with 6 samples.

How the data were processed

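Total RNA of 6 cultures of 293T cells was measured by RNA-seq, 3 after transfection of a miR-941 duplex and 3 after transfection of a scrambled control oligonucleotide. Per the labels' protocols, cells were plated 24 h before transfection with a cationic lipid reagent, and the miR-941 duplex was given at 10 nM. No concentration was recorded for the scrambled control. RNA was extracted with Trizol and depleted of ribosomal RNA, and libraries were sequenced over 100 bases from 1 end on an Illumina instrument. The time between transfection and RNA extraction is not given in the sources used here.

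The deposited values are whole-number counts per Ensembl gene, 1 table per library, with no normalization. The submitters' processing notes name STAR, edgeR and the human build hg19, with no versions. The counting program, the gene annotation and whether the counting used strand are not given in the sources used here. Each table lists only genes with at least 1 count, and a gene absent from a table was taken as 0. The union over the 6 libraries held 26613 genes, and each library listed 21617 to 22294 of them. Symbols were found for 25141 genes in a table of gene names, 25236 genes were present in GENCODE release 29, and 1377 had no symbol in either. No mitochondrially encoded gene was listed, so the share of mitochondrial reads could not be used as a sign of RNA quality. The most abundant transcript took 3.73% to 4.06% of the counts of a library, and the 10 most abundant 5.87% to 6.26%.

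Total counts per library ranged from 6079420 to 7651046. At this depth 3 counts correspond to 0.392 to 0.493 CPM. PCR duplicates could not be removed, since the tables hold no molecular identifiers. Libraries of the same group were compared by a chi-square test of their counts over genes with at least 20 counts. Every pair differed by more than sampling noise, with 1.27 to 2.38 times the variation that sampling alone gives, against 3.57 to 4.8 times for pairs from different groups. The labels call the transfections independent replicates, so each library was counted as 1 replicate.

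Samples were grouped by their titles. Counts were filtered with edgeR's filterByExpr by group, which kept 15607 genes and 99.7% of the counts, and scaled with TMM factors, which lay between 0.994 and 1.01. The main test was edgeR's quasi-likelihood test with robust dispersions and a design with the group only, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM values are scaled with the TMM factors, errors of CPM are SDs over 3 libraries, and errors of log2 fold changes are standard errors derived from the test statistic. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and mgcv 1.9.3.

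The gene lists, 8 genes and the rule that selects the other named genes were fixed before the data were examined. Of 28 lists, 23 had at least 5 tested members and were tested with limma's camera, with a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2. Benjamini-Hochberg adjustment ran over the 23 lists. Camera asks whether a list shifted in a shared direction, and not whether more of its members changed than of all genes. Camera with an estimated correlation and limma's fry were run beside it, and members were counted with adjustment over all genes and over the list alone. The named genes were, in each direction, the 12 with the largest change among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. To these were added up to 4 changed members per list by smallest p (up to 2 members, given as values, where none passed), 8 genes fixed by name, and the 5 fallen genes with a seed site and the smallest p. Some genes that the rule names are not reported here. Of these 119 genes, 21 had exons that overlap those of another tested gene in GENCODE release 29, and in 12 the partner had at least 25% of the named gene's level.

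The sequence of miR-941 was taken as the mature strand found in 5 annotated microRNA transcripts. Sites were searched in the longest annotated 3′ UTR of each gene in GENCODE release 29 (GRCh38), which gave 13110 tested genes with a 3′ UTR. This build differs from the hg19 of the authors' processing, so only sequence matches made here carry coordinates. The set of genes with the site complementary to bases 2 to 8 was tested with camera against all tested genes. Its mean and median were ranked among control 7-mers of the same base composition and CpG number, and the share of called genes was compared by Fisher's exact test. For the rank, log2 fold changes of 13098 genes with at least 20 bases of 3′ UTR were adjusted by a linear fit on log 3′ UTR length, GC content and expression. The same adjusted values were used to scan all 6-mers, 7-mers and 8-mers present in at least 30 genes.

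The gene test was tested on simulated counts drawn from the means and totals of these libraries, with 200 of the genes changed and 15470 passing the filter. It called 34% of 50 genes changed 1.2-fold and 70% of those changed 1.5-fold in the planted direction. It called 94% of those changed 2-fold and 96% of those changed 3-fold, and 2 of its 149 calls were unchanged genes. Every simulated gene was given the same biological coefficient of variation, 3.82%, whereas real genes differ in theirs. These rates therefore do not cover genes that vary more. A planted list of 30 genes shifted by 0.2 on the log2 scale was called by camera, and in simulated data without changes 0 of 23 lists were called. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.57. The simulation therefore cannot show how often camera calls lists whose members vary together. A 7-mer with a planted shift of −0.04 on the log2 scale had rank 1 in 1 simulation and rank 6 in another.

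Alternatives fixed before the data were examined were DESeq2 size factors, library totals, other filters, a replicate block, an offset smooth in GC content and length fitted with mgcv (available for 96.7% of tested genes), DESeq2's Wald test, limma-voom, other thresholds, other kinds of seed site, other set tests and leaving out each library in turn.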

Results

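The data were gene-level RNA-seq counts from 6 libraries of 293T cells, a readily transfected derivative of the human embryonic kidney line HEK293. In 3 libraries the cells had received a duplex that mimics the microRNA miR-941 at 10 nM, and in the other 3 a scrambled oligonucleotide, called the mock group here. A mimic duplex delivers a microRNA strand to the Argonaute proteins, which then lower mRNAs whose 3′ UTRs pair with bases 2 to 8 of that strand, the seed. The libraries were made from RNA depleted of ribosomal RNA and read over 100 bases from 1 end. The mimic libraries held 7651046, 7168077 and 6401918 counts and the mock libraries 7405330, 7178783 and 6079420. All 6 libraries came from transfected cells, so each difference below is between cells given the 2 oligonucleotides. No concentration was recorded for the scrambled oligonucleotide, so a difference in dose cannot be told apart from one in sequence. The labels describe the transfections as independent replicates.

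The first comparison asked which genes differed between cells given the miR-941 mimic and cells given the scrambled oligonucleotide. FKBP1A, which encodes the prolyl isomerase bound by FK506 and rapamycin, fell to 60.7 ± 1.38 CPM (SD, n = 3) from 227 ± 3.23 CPM in the mock group. TPM4, an actin-binding tropomyosin, rose to 425 ± 31.1 CPM from 175 ± 3.07 CPM. GANAB, a subunit of the glucosidase that trims glycoproteins in the endoplasmic reticulum, rose to 766 ± 50.9 CPM from 363 ± 10.8 CPM. Of 15607 genes tested, 1061 rose and 966 fell, together 12.99%, and most of these changes were small. The median absolute log2 fold change of the changed genes was 0.29, and 23 risen and 13 fallen genes changed at least 2-fold.

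**Figure D1:**
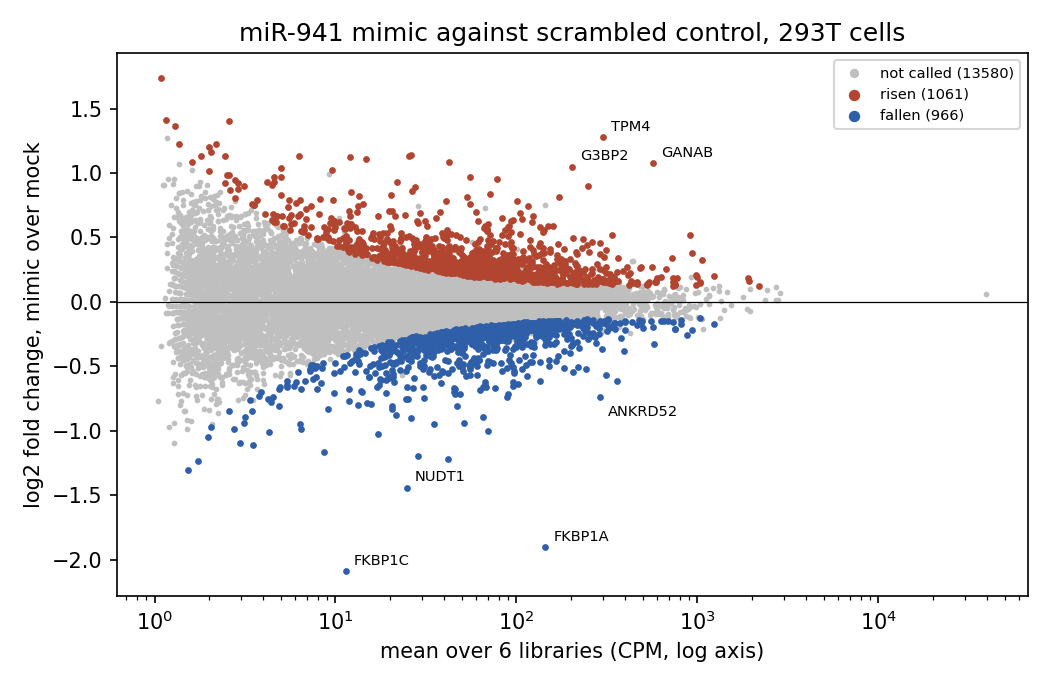
Log2 fold change of each of the 15607 tested genes (mimic over mock) against its mean level over the 6 libraries in CPM, on a log axis. The 1061 risen genes are red, the 966 fallen genes blue and the 13580 genes without a call grey, with FKBP1A at −1.90 and TPM4 at 1.28.

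The calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 3979 genes had an unadjusted p under 0.05. In 4418 genes, or 28.3%, all mimic libraries lay on one side of all mock libraries, where chance gives 10%, and 1924 of the changed genes were among these. The spread between replicates was low, with a biological coefficient of variation of 3.82%. DESeq2's Wald test called 1015 genes, 516 risen and 499 fallen, and gave no adjusted p to 3934 of the tested genes. Without mock replicate 1 the edgeR count was 1302 genes, 689 risen and 613 fallen, and without mock replicate 3 the number of fallen genes was 631.

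The 12 risen genes selected for the largest change covered several cell functions. TPM4 had a log2 fold change of 1.28 ± 0.05 (SE), with an adjusted p of 1.12e-31 by edgeR's quasi-likelihood test. HABP4, which encodes an RNA- and hyaluronan-binding protein, rose by 1.14 ± 0.10, and CHST14, a sulfotransferase of dermatan sulfate synthesis, by 1.13 ± 0.10. Proteins of the endoplasmic reticulum were represented by GANAB (1.08 ± 0.05), EMC6 of the membrane protein insertion complex (1.08 ± 0.08) and the chaperone MESD (0.95 ± 0.06). G3BP2, a stress granule protein, rose from 131 ± 2.51 to 272 ± 8.33 CPM. RGS19, a regulator of G protein signalling, rose from 6.32 ± 0.53 to 12.8 ± 0.62 CPM. The zinc-finger gene ZNF616 rose from 9.35 ± 1.03 to 20.1 ± 2.02 CPM. Among the 12 were also the pseudogenes TPM4P3 (1.13 ± 0.19) and AC098614.1 (1.12 ± 0.14). TPM4P3 is annotated as a processed pseudogene of TPM4, so that the 2 can share reads and its change is uncertain. Exons of EMC6 and HABP4 overlap those of P2RX5-TAX1BP3 (log2 fold change 0.45) and CDC14B (−0.11) on the opposite strand, and whether the counting used strand is not given in the sources used here.

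Of the 12 fallen genes selected by the same rule, FKBP1A had the smallest p, with a log2 fold change of −1.90 ± 0.06 and an adjusted p of 3.89e-39 by edgeR's quasi-likelihood test. FKBP1C, a near copy of FKBP1A, had the largest change, −2.09 ± 0.16, from 18.4 ± 0.79 to 4.34 ± 1.35 CPM. It shares read-length stretches with FKBP1A and is uncertain. NUDT1, the enzyme that clears oxidised purine nucleotides, fell from 36.2 ± 1.97 to 13.3 ± 3.26 CPM. AGPAT5, an acyltransferase of phospholipid synthesis, changed by −1.22 ± 0.08, in log2 units. The small heat shock protein gene HSPB8 changed by −1.20 ± 0.10, RGS10, another regulator of G protein signalling, by −1.16 ± 0.17, and the membrane protein gene TMEM109 fell from 92.4 ± 6.04 to 46.3 ± 4.05 CPM. VPS37B, a subunit of the ESCRT-I sorting complex, changed by −0.95 ± 0.09, cyclin A1 (CCNA1) by −0.95 ± 0.20 and CYBA, a subunit of the phagocyte NADPH oxidase, by −0.94 ± 0.07. SPRYD3 changed by −1.02 ± 0.12, and its exons overlap those of TNS2 (log2 fold change 0.04) on the opposite strand. The unnamed gene ENSG00000256152 changed by −0.99 ± 0.19. Its exons overlap those of VPS37B on the opposite strand, and VPS37B was counted at 545% of its level, so its change is uncertain.

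**Figure D2:**
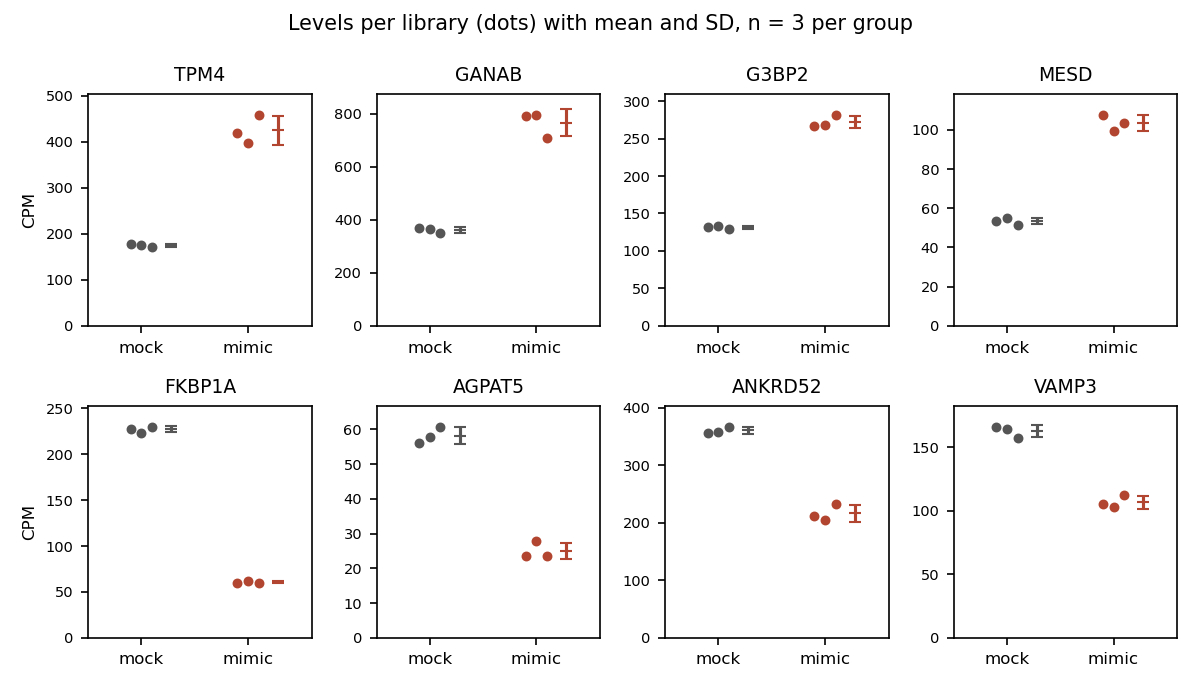
Levels in CPM of 8 genes in the 3 mock and 3 mimic libraries (dots), with the mean and SD of each group beside them. TPM4, GANAB, G3BP2 and MESD were higher in every mimic library than in any mock library, and FKBP1A, AGPAT5, ANKRD52 and VAMP3 were lower.

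The second comparison asked whether mRNAs with a 3′ UTR site for the miR-941 seed were lower after the mimic. The mature miR-941 strand used was CACCCGGCUGUGUGCACAUGUGC, and the site complementary to its bases 2 to 8 is GCCGGGT. Genes with this site in the longest annotated 3′ UTR fell more often than genes without it. Of 706 such genes 81 fell, or 11.5%, against 838 of 12392, or 6.76%, without it, while 7.22% and 7.50% rose. The change per gene was small, with a median log2 fold change of −0.02 over the 706 genes. An 8mer site, in which an A follows the 7 bases, was present in 72 genes, of which 14 fell, or 19.4%, and 5 rose.

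The 5 fallen genes with a GCCGGGT site and the smallest p were ANKRD52, NUDT1, CERK, VAMP3 and VPS37B. ANKRD52, a subunit of protein phosphatase 6, fell from 360 ± 5.69 to 216 ± 14.3 CPM, with an adjusted p of 8.42e-20 by edgeR's quasi-likelihood test. Its site lies on chromosome 12 at 56240918 to 56240924 on the minus strand of GRCh38, in the last of 28 exons and 2218 bases into a 3′ UTR of 5335 bases. CERK, which makes ceramide 1-phosphate, fell from 111 ± 5.62 to 67.9 ± 3.35 CPM. Its site lies on chromosome 22 at 46685851 to 46685857 on the minus strand, 1277 bases into a 3′ UTR of 2723 bases in exon 13 of 13. VAMP3, a SNARE of recycling endosomes, fell from 163 ± 4.59 to 107 ± 5.01 CPM. Its site lies on chromosome 1 at 7781267 to 7781273 on the plus strand, 1622 bases into a 3′ UTR of 1787 bases in exon 5 of 5. The NUDT1 site lies on chromosome 7 at 2251089 to 2251095 on the plus strand, 88 bases into a 3′ UTR of 144 bases in exon 3 of 3. The VPS37B site lies on chromosome 12 at 122866916 to 122866922 on the minus strand, 194 bases into a 3′ UTR of 1788 bases in exon 4 of 4. All 5 are 7mer sites without the following A, and the positions come from a sequence match to the GENCODE release 29 transcripts on GRCh38.

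**Figure D3:**
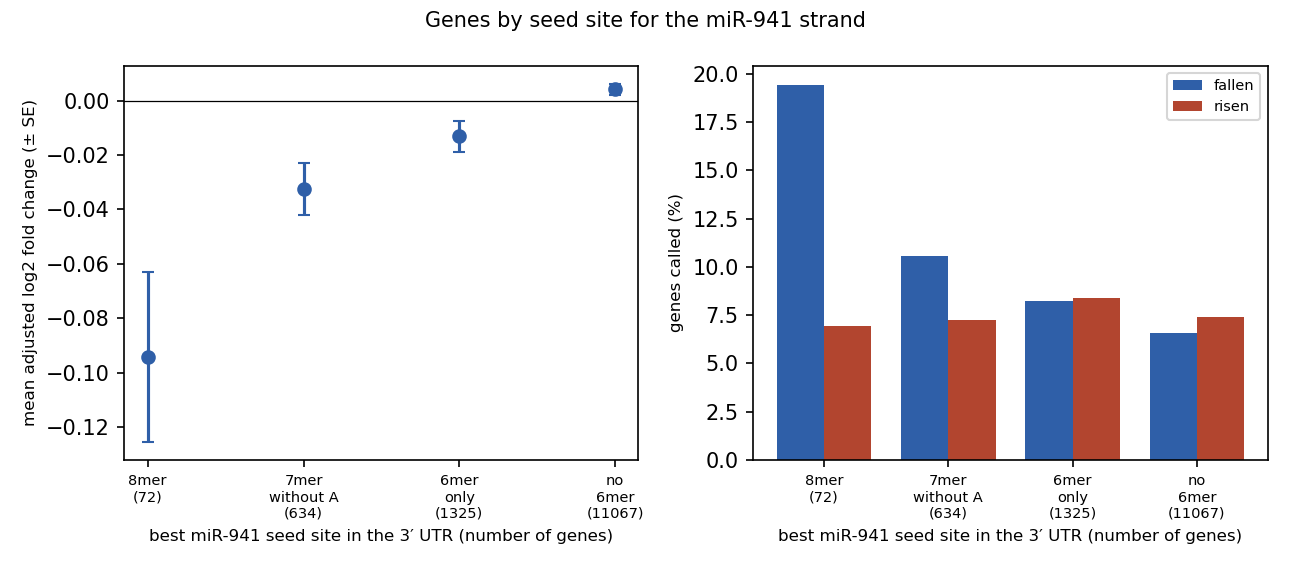
Genes by the best miR-941 seed site in the 3′ UTR, with the mean adjusted log2 fold change and its SE over genes (left) and the share of genes called fallen or risen in percent (right, bars from 0). The mean was −0.094 for 72 genes with an 8mer, −0.032 for 634 genes with a 7mer, −0.013 for 1325 genes with a 6mer and 0.00405 for 11067 genes with none.

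The higher share of fallen genes among those with a GCCGGGT site had a Fisher exact p of 9.49e-06, two-sided, or 2.28e-05 with Benjamini-Hochberg adjustment over 12 such tests. After adjustment for 3′ UTR length, GC content and expression, the mean log2 fold change of the 706 genes was −0.039 ± 0.009 (SE over genes, which are not independent replicates). It lay below the means of all 59 control 7-mers with the same bases and the same number of CpG pairs, which ranged from −0.024 to 0.014, and the median was also below all of theirs. The resulting empirical p of 0.0167 is the smallest that 59 controls can give. The difference in mean log2 fold change between the whole group and all other genes was −0.042, and limma's camera test with a preset correlation of 0.01 between genes did not pass (p = 0.0997). Nor did it pass with an estimated correlation (p = 0.146), or at the preset correlation after adjustment for 3′ UTR length, GC content and expression (difference −0.041, p = 0.0725). At the preset correlation it passed with an offset for GC content and length (p = 0.0212), with that offset and the replicate block (p = 0.0284), and for 8mer sites alone (p = 0.00379). Sites in the coding sequence and the 5′ UTR gave differences of 0.0058 and 0.0028 with camera p of 0.803 and 0.774, against the negative difference for the 3′ UTR. After the same adjustment as for 3′ UTRs, the 812 genes with GCCGGGT in the coding sequence had a mean of −0.0114, also negative, and 1 of 59 control 7-mers was as low. Their unadjusted median, 0.006, was below those of all 59 controls, as in the 3′ UTR.

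The third set of comparisons took gene lists fixed before the data were examined. The hedgehog and insulin pathways were included because earlier work on miR-941 had linked it to them. In the hedgehog list, 3 of 36 tested members rose and 3 fell, with CDON, a co-receptor for hedgehog ligands, at −0.40 ± 0.09. Adjusted over the list alone, 3 rose and 4 fell. SMO, the signal transducer of the pathway, fell to 59.1 ± 4.77 CPM from 70.1 ± 2.47 CPM, with a log2 fold change of −0.24 ± 0.07 and an adjusted p of 0.0103 by edgeR's quasi-likelihood test. That call ended under DESeq2 (adjusted p = 0.0645), without mock replicate 2 (0.0528) and without mock replicate 3 (0.0513). The inhibitor SUFU had a log2 fold change of −0.02 ± 0.09 and the target gene GLI1, at 3.49 ± 0.29 against 3.03 ± 0.68 CPM, of 0.20 ± 0.26, and neither passed. No shared shift of the list against other genes was called by camera (adjusted p = 0.863).

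In the insulin signalling list, 6 of 53 tested members rose and 5 fell, and 8 rose and 6 fell when adjusted over the list alone. IGF2, a growth factor ligand, rose from 8.68 ± 0.78 to 15.7 ± 0.79 CPM, and glycogen synthase (GYS1) changed by 0.39 ± 0.06. The adaptor GRB2 changed by −0.49 ± 0.05, and the kinase RPS6KB2 fell from 80.3 ± 4.42 to 56.9 ± 2.84 CPM. GRB2 has 2 GCCGGGT sites in its 3′ UTR and RPS6KB2 has 1, but RAC1 and XPC, selected from the adhesion and p53 lists, have 1 each and rose, by 0.42 ± 0.05 and 0.28 ± 0.07 (XPC: adjusted p = 0.0505 without mock replicate 3). Exons of XPC overlap those of LSM3 (log2 fold change 0.03) on the opposite strand, counted at 138.3% of its level, so its change is less certain. INSR (−0.01 ± 0.07), IRS1 (−0.09 ± 0.07), FOXO1 (−0.16 ± 0.11) and PPARGC1A (−0.03 ± 0.18) did not pass, with adjusted p of 0.965, 0.472, 0.402 and 0.948 by edgeR's quasi-likelihood test. No shared shift of the list was called (camera adjusted p = 0.938), which does not speak to members that moved in opposite directions. In the list of neurotransmitter release, DNAJC5, a synaptic vesicle co-chaperone, fell from 123 ± 4.03 to 104 ± 7.07 CPM with an adjusted p of 0.00187. Of its 25 tested members 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.21).

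Genes of the unfolded protein and integrated stress responses were higher in the mimic group. Of 26 tested members 12 rose and none fell by edgeR's quasi-likelihood test, and 14 rose when adjusted over the list alone. The endoplasmic reticulum chaperones CALR and HSP90B1 rose from 815 ± 8.79 to 1058 ± 41.3 CPM and from 946 ± 46.3 to 1184 ± 45.8 CPM. The stress transcription factor ATF4 changed by 0.27 ± 0.05, and its target TRIB3 rose from 35.8 ± 3.23 to 51.4 ± 3.15 CPM. The median log2 fold change was 0.20 (camera adjusted p = 2.4e-05, and adjusted p = 0.542 with an estimated correlation). Among heat shock genes 2 of 12 rose and 1 fell, also when adjusted over the list alone. HSPD1 changed by 0.27 ± 0.04 and the co-chaperone BAG3 by −0.29 ± 0.06, and no shared shift of the list was called (camera adjusted p = 0.317).

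Immediate early genes were also higher, with 7 of 26 tested members risen and none fallen, both over all genes and adjusted over the list alone. The matricellular genes CCN1 and CCN2 rose from 79.4 ± 7.49 to 129 ± 7.36 CPM and from 127 ± 5.69 to 192 ± 11.8 CPM, and IER2 changed by 0.56 ± 0.08. The list's camera adjusted p was 0.00734, and its adjusted p = 0.542 with an estimated correlation. It was 0.0534 when only genes with a mean of at least 5 CPM were kept. Of 13 tested replication-dependent histone genes 2 rose and none fell, also when adjusted over the list alone. These were H2BC5, from 3.25 ± 0.38 to 6.70 ± 0.63 CPM, and H2BC11, from 8.84 ± 1.30 to 12.2 ± 2.04 CPM. The histone list had a camera adjusted p of 0.0254, and an adjusted p = 0.542 with an estimated correlation. Its call ended without mimic replicate 1 (0.164), without a filter on low counts (0.112) and with the filter at 5 CPM (0.173), and that of H2BC11 under DESeq2's Wald test (0.154) and without mimic replicate 1 (0.259), mock replicate 1 (0.115) or mock replicate 2 (0.12).

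Genes listed as targets of the tumour suppressor p53 were lower in the mimic group, while the activity of p53 itself was not measured. Of 23 tested members 7 fell and 1 rose, and 8 fell and 2 rose when adjusted over the list alone. The cyclin-dependent kinase inhibitor CDKN1A fell from 227 ± 9.07 to 180 ± 2.29 CPM, the RNA-binding protein gene ZMAT3 from 44.7 ± 1.74 to 30.3 ± 2.64 CPM and TP53INP1 from 34.9 ± 0.93 to 25.2 ± 2.84 CPM. The median was −0.15 (camera adjusted p = 0.0177, and adjusted p = 0.542 with an estimated correlation). Without mock replicate 3 the camera adjusted p was 0.0877. Genes of the G2 and M phases had 5 fallen and no risen members of 26, and 6 fallen and 1 risen adjusted over the list alone, but the list did not pass (camera adjusted p = 0.0667, and adjusted p = 0.717 with an estimated correlation). It passed without mock replicate 3 (0.0187) and without a filter on low counts (0.0395). The mitotic kinases PLK1 and AURKA fell from 243 ± 5.21 to 166 ± 8.91 CPM and from 128 ± 4.34 to 95.9 ± 4.36 CPM. Among S phase genes 5 of 25 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone, with E2F1 at −0.33 ± 0.06 and CCNE1 at −0.35 ± 0.08. No shared shift of that list was called (camera adjusted p = 0.57), with a mean of −0.04 and a median of 0.03.

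Nuclear genes of oxidative phosphorylation and genes of cytosolic ribosomal proteins shifted down by small amounts. In the first list 13 of 58 members fell and 4 rose, and 21 fell and 4 rose when adjusted over the list alone. COX7B fell from 183 ± 8.71 to 158 ± 5.26 CPM. The camera adjusted p was 0.00478, and the adjusted p = 0.717 with an estimated correlation. Of 70 ribosomal protein genes 10 fell and 1 rose, with the same counts adjusted over the list alone. RPL34 changed by −0.25 ± 0.06 (adjusted p = 0.101 without mock replicate 3), and RPL11 was the member that rose, by 0.19 ± 0.04. The camera adjusted p was 0.00734, and the adjusted p = 0.717 with an estimated correlation. The ribosomal list's call ended without mimic replicate 3 (0.331) and without mock replicate 1 (0.143). Mimic replicate 3 lay apart from the other mimic libraries on the second principal component, at −18.9 against 8.44 and 13.6. Mock replicate 3 lay apart from the other mock libraries on the third, at 18.6 against −11.6 and −8.31. The glycolysis and hypoxia list, with 3 of 29 members risen and none fallen, also adjusted over the list alone, had a camera adjusted p of 0.0667, and an adjusted p = 0.724 with an estimated correlation. The camera adjusted p was 3.87e-06 without mimic replicate 3, 0.0126 without mock replicate 1, 0.0395 without a filter on low counts and 0.0321 with the replicate block. PFKL, a subunit of phosphofructokinase, changed by 0.34 ± 0.06.

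The remaining lists did not pass camera. Among small RNA silencing genes 6 of 18 fell and 2 rose, and 7 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.317). TNRC6C and TNRC6A, partners of Argonaute proteins, fell by 0.58 ± 0.08 and 0.23 ± 0.05 on the log2 scale, and the nuclease DROSHA rose by 0.26 ± 0.05. Of 35 genes of the interferon and double-stranded RNA response 1 fell and none rose, also adjusted over the list alone. The fallen gene was the ubiquitin ligase gene TRIM25 (−0.26 ± 0.05), whose exons overlap those of DGKE (0.14) on the opposite strand (list adjusted p = 0.825). None of 11 NF-kB and inflammatory target genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.938, direction up, with a mean of −0.02). Of 25 cholesterol genes 6 rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone, with HMGCS1 at 0.26 ± 0.05 and INSIG1 at 0.44 ± 0.06. That list had a camera adjusted p of 0.0948, of 0.044 without mimic replicate 3 and of 0.717 with an estimated correlation.

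Signalling and adhesion lists moved both ways, and none of those that follow passed camera. Of 28 TGF-beta and SMAD genes 5 rose and 5 fell, and 5 rose and 7 fell adjusted over the list alone, with LTBP1 at 0.35 ± 0.07 and the inhibitor SMAD7 at −0.28 ± 0.06 (camera adjusted p = 0.317). Of 32 Wnt and beta-catenin genes 5 rose and 2 fell, with the same counts adjusted over the list alone, with TCF7L1 at 0.49 ± 0.12 and LEF1 at −0.42 ± 0.10. That list's adjusted p was 0.937, with a mean of 0.02 and a median of −0.0058. Of 25 Notch genes 4 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.21). Of 38 adhesion and migration genes 6 rose and 4 fell, and 6 rose and 5 fell adjusted over the list alone. RAC1 rose, as did FN1 by 0.20 ± 0.04 (list adjusted p = 0.346). Of 28 apoptosis regulators 2 rose and 2 fell, also adjusted over the list alone. The apoptosis list had an adjusted p of 0.61, with a mean of 0.0090 and a median of −0.05.

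Leukocyte and hepatocyte markers were scarce, while some fibroblast markers and keratins were counted at higher levels. Of 6 tested markers of epithelial carcinoma lines 2 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.23, 0.0293 without mimic replicate 1 and 0.717 with an estimated correlation). KRT17 fell from 158 ± 15.9 to 131 ± 10.9 CPM, with an adjusted p of 0.0532 without mock replicate 1, and KRT19 from 155 ± 0.07 to 136 ± 4.52 CPM. Leukocyte and hepatocyte markers did not exceed 2.97 and 0.558 CPM in any library, fibroblast markers reached 41.02 CPM (all 3 from library totals, without TMM factors), and 4 fibroblast markers, 2 leukocyte markers and 0 hepatocyte markers had enough counts to be tested. No list of these 3 was large enough for camera. Of the 17 names in the list of abundant non-coding RNAs only MALAT1 and NEAT1 matched a counted gene. Their log2 fold changes were 0.75 ± 0.24 and 0.25 ± 0.14, with adjusted p of 0.144 and 0.358 by edgeR's quasi-likelihood test. Genes annotated as lincRNA took 3.98% to 4.31% of the counts of a library, most of it from outside these 2. In all 6 libraries this share lay slightly above that of the most abundant gene, 3.73% to 4.06%. Whether 1 lincRNA made up most of it was not examined. No mitochondrially encoded gene was listed in the files.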

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

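In this part, the runs with genes that have a 3′ UTR as the background, without zinc-finger genes and over genes without 2 other sites were chosen after the data had been seen, and the other settings before. The number of changed genes stayed between 1819 and 2744 under other scalings, filters, limma-voom, GC offset, replicate block and an adjusted p of 0.1. DESeq2's Wald test called 1015 genes (516 risen, 499 fallen), of which 1014 were among the 2027. It gave no adjusted p to 3934 of the tested genes, which it could therefore not call. An absolute log2 fold change of at least 0.5 left 328 (181 risen, 147 fallen) by construction. Without 1 library the count ranged from 1302 to 2061 genes, with 689 to 1080 risen and 613 to 981 fallen, where fewer libraries enter the fit. Among genes whose 3′ UTR holds neither GCACATG nor TCGGAGA, 1464 changed, 787 risen and 677 fallen.

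Samples with the same replicate number did not deviate together: the correlations across genes were 0.044, −0.051 and −0.017. Not every sample correlated best with its own number. The counts thus gave no sign of pairing by number, which does not show whether same-numbered transfections were done together. The fit with a replicate block called 1819 genes, 965 risen and 854 fallen, of which 1791 were among the 2027. It gave a seed-site difference of −0.042, still short of the threshold, and called 7 lists.

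The seed-site set kept its negative difference in mean log2 fold change and missed its threshold in other scalings and filters, with −0.034 to −0.049 without 1 library, with −0.038 against genes with a 3′ UTR and with −0.044 without zinc-finger genes. It passed at −0.056 with the GC and length offset, at −0.056 with that offset and the replicate block, and at −0.098 for 8mer sites. The differences for coding-sequence and 5′ UTR sites were 0.0058 and 0.0028, but the adjusted mean for coding-sequence sites was −0.0114. The cause of these shifts was not tested. Between 4 and 7 lists were called under scalings, filters and blocks and 6 or 7 without 1 library, but 0 with an estimated correlation (1 list with an unadjusted p under 0.05) and 0 by fry (8 lists with an unadjusted p under 0.05, smallest adjusted p 0.0534). Camera called 6 lists, with 9 at an unadjusted p under 0.05.

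Lists whose difference in mean changed sign were all without a call. Without a filter on low counts the hedgehog list was at −0.069, heat shock at −0.28 and Wnt at −0.022. With genes of at least 5 CPM, NF-kB was at 0.014 and Wnt at −0.038. With the GC and length offset, insulin was at −0.0047 and Wnt at −0.014, and with the replicate block added at −0.0051 and −0.014. Without 1 library, insulin ranged from −0.0022 to 0.019, hedgehog from −0.0042 to 0.027, Wnt from −0.0031 to 0.022 and apoptosis from −0.0071 to 0.0067. Log2 fold changes ranged from −0.058 to 0.042 for INSR, from −0.19 to 0.089 for PPARGC1A and from −0.050 to 0.0048 for SUFU. Of 105 called genes that the naming rule selects, 25 lost their call without at least 1 library, 14 under DESeq2 and 3 with the replicate block. In every setting run for them 80 kept it, including all 27 selected for their size of change or seed site. A gene without an adjusted p in a setting was not counted as lost there.

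The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2027 genes and the highest of the others 0, so 1 split gave as many. For the seed-site difference 1 split, the real one, reached 0.042, and the highest other gave 0.030. For the lists 2 splits called as many as 6, since the split that put mimic replicates 1 and 2 with mock replicate 1 also called 6. The remaining splits, which each keep part of the group difference, called 0 to 5 lists, most of them 3, although none called a gene. The number of lists called is thus not particular to the real grouping. At 6079420 to 7651046 counts per library, changes of 1.2-fold were called for 34% of simulated genes, all given the same variation. That limits what the data can show of small effects, and the share does not cover genes that vary more.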

Other observations

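Of the tests in this part, the zinc-finger comparison, the scan of all 7-mers and both tests against control 7-mers were chosen only after the results had been seen. Zinc-finger genes, taken by name (ZNF, ZFP, ZSCAN and ZKSCAN), were higher as a group in the mimic libraries. Of 512 tested, 102 rose (19.9%) and 4 fell by edgeR's quasi-likelihood test, against 959 risen of 15095 other genes (6.35%), with a Fisher exact p of 1.41e-23. The median log2 fold change was 0.12, against −0.0017 for other genes, and camera gave p = 3.14e-10 and p = 0.00222 with an estimated correlation. Examples chosen after their values were seen are ZNF629, which rose from 65.1 ± 2.26 to 102 ± 2.47 CPM (SD, n = 3; edgeR adjusted p = 2.44e-13), ZNF875, which rose from 67.1 ± 3.57 to 92.7 ± 2.22 CPM, and ZNF703, which fell from 83.0 ± 9.32 to 52.4 ± 3.83 CPM. The median stayed between 0.114 and 0.13 under other scalings, the GC and length offset, the replicate block and without any 1 library, while the number of risen genes was 56 without mock replicate 1. The other 9 splits of the libraries, which each keep part of the group difference, gave absolute medians of 0.0288 to 0.0625 and camera p of 1.26e-04 to 0.165, under 0.05 in 7 of them. Chromosome 19 holds 235 of these genes, and its other tested genes had a median of 0.03, against 0.09 for zinc-finger genes on other chromosomes. No autosome, nor the X chromosome, had a median beyond −0.0235 to 0.0582.

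Among all 16383 7-mers present in at least 30 of the 3′ UTRs, GCACATG had the lowest z score of the adjusted log2 fold change and the miR-941 seed site GCCGGGT rank 2 from the low end. TCGGAGA had rank 3 from the high end (z of 8.70), after CGGAGAA and GGAGAAA and before TGGAGAA (8.41) and AAGGAGA (6.99). Among 6-mers CGGAGA (10.3) and GGAGAA (9.30) were highest, ahead of TCGGAG (6.89). Of the 919 fallen genes with a 3′ UTR, 287 (31.2%) held GCCGGGT or GCACATG, against 16.7% of genes without a call, and of the 980 risen genes 86 (8.78%) held TCGGAGA, against 2.67%. GCACATG and TCGGAGA were picked from these same values, so their part of these shares was favoured by that choice.

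GCACATG occurred in 1801 genes, of which 232 (12.9%) fell against 6.08% of the rest, with a mean adjusted log2 fold change of −0.033, and 395 genes with GCACATGA had a mean of −0.078. It is the site for the seed of a strand fully complementary to miR-941 with overhangs of 2 bases. It is also complementary to bases 17 to 23 of miR-941 itself, the end away from the seed. The 299 control 7-mers of the same bases had a median of 0.0004 in 3′ UTRs, and 2 of them (0.67%) reached 0.5 of the mean of GCACATG. The median argues against these bases alone lowering such genes. The share reaching 0.5 and the lead over the controls carry no weight, since GCACATG was picked as the lowest of the same scan. Coding sequences with GCACATG had a mean of −0.0118, as low as the lowest 4.35% of controls, although their unadjusted median was 0.0051. A candidate explanation is that the second strand of the duplex also acted through its own seed, which stays a hypothesis, since the labels do not give the sequence of that strand. Pairing with the other end of the miR-941 strand was not tested apart from it.

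TCGGAGA occurred in 401 genes, of which 86 (21.4%) rose against 7.04% of the rest. The mean was 0.093, and 0.18 for the 118 genes with TCGGAGAA. Of the 12 risen genes selected for the largest change 10 have a 3′ UTR, and 5 of these hold it there, TPM4, HABP4, CHST14, ZNF616 and G3BP2, while GANAB, RGS19 and MESD hold GCACATG there although they rose. Zinc-finger genes (a mean of 0.0929 without them) are argued against as the source. So is weaker action of endogenous microRNAs, since the highest of 10 families reached a ratio of 0.0086 to TCGGAGA. The 179 control 7-mers with the same bases and CpG number had a median of 0.0058, and 2 of them, or 1.12%, reached 0.5 of the mean of TCGGAGA. The median argues against these bases alone raising such genes. The share reaching 0.5 carries no weight, since TCGGAGA was picked from the same scan. The controls also leave out GGAGAAA and TGGAGAA, which hold no CpG and had means of 0.0279 and 0.0258. A wider GGAGAA pattern was thus not tested, and a TCGGAGA seed would not cover it. A candidate explanation is that a strand of the scrambled control lowered its own seed matches in the mock libraries: coding sequences with the 7-mer also had a positive mean, 0.0544, above all 179 controls. Its sequence is not given in the sources used here, and without untransfected cells a rise in the mimic group cannot be parted from a fall in the mock group.

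FKBP1A and its near copy FKBP1C had the most negative log2 fold changes of the named genes, −1.90 and −2.09. FKBP1A holds 1 GCACATG in its 3′ UTR, and its longest uninterrupted match to either strand's site is 11 bases (ACATGTGCACA), a length that 5.158% of the genes searched reach. Extended pairing may contribute, but a match this common decides nothing. For FKBP1C, 13.58% of its read-length windows are found in FKBP1A transcripts, too few for shared reads to be shown as the source of its change and too many to leave them out. Both explanations stay open and cannot be told apart from an effect of the mimic outside direct pairing.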
